A study of Mus musculus with 2 samples.

How the data were processed

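The 2 libraries are microRNA-seq of total RNA from hippocampus tissue of B6CASTF1/J male mice, 1 library per labelled biological replicate. Each file holds raw counts per microRNA gene, deposited by the authors without normalization. Small RNA reads were mapped to mm10 and counted against the microRNA genes of GENCODE M21, per the notes deposited with the count files. The aligner and its version are not given in the sources used here. The layout of the deposited counts, with unmapped, multimapping, no-feature and ambiguous reads ahead of the genes and with 1 count column for either strand, 1 for the strand of the gene and 1 for the opposite strand, was read from the values. No header names these columns. The lines that name no gene were left out of library sizes and tests. They held 64.7% of the reads in replicate 1 and 65.4% in replicate 2.

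Counts on the strand of the gene were used throughout, since the either-strand column sets aside reads where 2 microRNA genes overlap on opposite strands. All 2202 gene identifiers matched GENCODE M21, and coordinates, overlaps and hairpin sequences come from that annotation on mm10. The position of a gene in an intron or exon refers to genes on its own strand. Mature arms cannot be separated, because the counts are per gene. Reads that match several places are not assigned to genes, which can lower the counts of genes with near-identical copies. Both replicates carry the alleles of CAST/EiJ beside those of the reference strain, and the effect of such variants on mapping was not tested.

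CPM is the count divided by the library's own-strand total over all genes, times 1000000. Levels are given as mean ± SD of the 2 libraries. The libraries were compared gene by gene with a two-sided exact conditional binomial test in scipy 1.17.1, with the expected share from TMM-adjusted library sizes (edgeR 4.0.16, R 4.3.3; factors 0.994 and 1.01), over genes with 10 or more counts in total and with Benjamini-Hochberg adjustment at 0.05. Log2 ratios are replicate 2 over replicate 1 after TMM, with 1 CPM added to each. The test covers counting error only. edgeR's quasi-likelihood test needs a contrast between groups, and there is 1 group. The spread between the libraries is the square root of edgeR's common dispersion in an intercept-only design. DESeq2 1.42.0 gave the alternative size factors and dispersion.

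The 16 gene lists and 18 sets of genes in 1 host transcript were fixed before the data were examined: neuronal, miR-9 and miR-181 families, oligodendrocyte, astrocyte and reactive glia, microglia and leukocyte, red blood cell, vessel wall, choroid plexus and ciliated epithelium, neighbouring brain and sensory, muscle, liver with pancreas and pluripotent cell, let-7, miR-17 with paralogues, miR-30, Dlk1-Dio3 and Sfmbt2. Several markers, such as those of the astrocyte list, are also expressed by other brain cells. Older symbols in the annotation were matched for 3 members. The Sfmbt2 list holds every gene with a Mir297, Mir466, Mir467 or Mir669 symbol, without regard to its position. A list's level and its library difference are described by the percentile of its median among 10000 seeded random lists, the second matched on expression deciles. Near-identical copies are genes whose hairpin shares a stretch of 20 bases with another gene that it does not overlap. Only annotated microRNA genes were compared, and copies elsewhere in the genome were not searched.

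Genes named in the text are the 20 with the highest mean CPM, the 3 highest of each list, the 5 with the largest log2 ratio in each direction among genes with 100 or more counts past the threshold, and the members of the host transcript sets. Genes named outside this rule are counted families or are said to be chosen after their values were seen. The alternatives tried were the either-strand counts, other scalings, other count minimums, another pseudocount, added overdispersion, another source of random lists, other stretch lengths and each library alone.

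The library test was tested on simulated counts for replicate 2 against replicate 1, drawn from the real means and library sizes. Without overdispersion, over 501 genes, it recovered 60.9% of 1.5-fold, 65.9% of 2-fold, 100% of 4-fold and 96.3% of 8-fold changes and called 0.66% of unchanged genes. The beta-binomial form at a coefficient of variation of 0.3, over 514 genes, recovered 2.1%, 7%, 59.6% and 87%, and called 2.2% of unchanged genes. A simulated coefficient of variation of 0.3 was estimated as 0.288. Both simulated settings hold less spread than the 0.425 estimated between the real libraries, so these rates do not carry over to the real calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.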

Results

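MicroRNA-seq was performed on tissue labelled as a layer of hippocampus from male mice of the strain B6CASTF1/J, the F1 cross of C57BL/6J and CAST/EiJ, at an age of 36 days. The series holds 2 libraries of 1 group, labelled biological replicates 1 and 2. The labels state no question beyond the profile itself, and there is no second condition. The comparisons made here are the level of each microRNA gene, the levels of gene lists fixed before the data were examined, and replicate 2 against replicate 1. The replicates come from separate tissue samples under a shared donor label, so p-values between them describe these 2 libraries and not a condition. With 2 libraries the smallest two-sided exact sign-flip p is 0.5, so no level was tested against another across animals.

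Replicate 1 gave 4404040 counts on the strand of a microRNA gene and replicate 2 gave 5279877, which were 35.3% and 34.6% of 12462653 and 15241166 reads. Reads that matched several places made up 40.3% of replicate 1 and 46.5% of replicate 2, and these enter no gene's count. Unmapped reads made up 20.2% and 13.7%, and reads in no annotated microRNA gene 4.17% and 5.20%. A count of 0 allows up to 3 counts, or 0.681 CPM (counts scaled to a library of 1000000) in replicate 1 and 0.568 CPM in replicate 2. Intervals and floors given here cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Of the 2202 microRNA genes in the annotation used by the files, 411 had 10 or more counts in both libraries, 1424 had 0 counts in both, and 85 reached 1000 CPM in both.

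**Figure D1:**
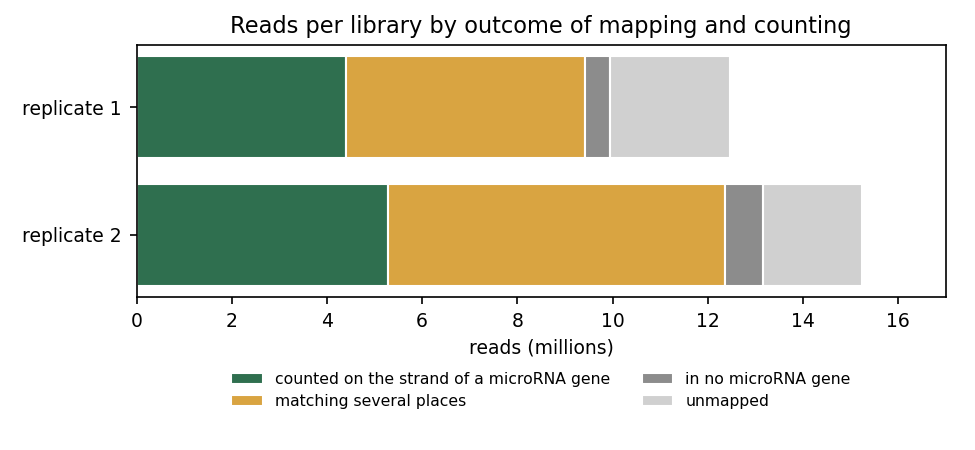
Reads per library on the horizontal axis, in units of 1000000 reads, split by outcome of mapping and counting, with 1 bar per replicate. Reads that matched several places outnumber those counted on the strand of a microRNA gene in both libraries, by 1.14 times in replicate 1 and 1.34 times in replicate 2.

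A small set of genes held most of the counts, led by the let-7 family, whose members are widely expressed in differentiated tissue. Reads that match several places are outside these counts, so genes with near-identical copies can rank too low. The 10 genes with the highest mean took 53.7% ± 3.65 of the counts (SD, n = 2), with 56.3% in replicate 1 (95% Wilson interval 56.26 to 56.35) and 51.1% in replicate 2 (51.10 to 51.19). Mirlet7g (ENSMUSG00000065440.1, in an intron of Wdr82 on chromosome 9, 106178840 to 106178927, mm10) was the highest gene at 104296 ± 13411 CPM. Mir139 (ENSMUSG00000065446.1), in an intron of the phosphodiesterase gene Pde2a on chromosome 7 at 101475376 to 101475443, followed at 84408 ± 15431 CPM. Mirlet7b reached 76603 ± 11336 CPM, Mirlet7i 65093 ± 13663 CPM and Mir127 56482 ± 1909 CPM (mean ± SD, n = 2, as for every level given as mean ± SD).

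Among the 20 highest genes, 5 belonged to the let-7 family and 5 to the imprinted Dlk1-Dio3 region, and 15 lay in an intron or exon of another gene on their strand. Mir132 (ENSMUSG00000065537.2, chromosome 11, 75173682 to 75173747), a microRNA whose transcription is known to follow neuronal activity, stood at 20543 ± 4655 CPM. Mir744, in an intron of Map2k4, stood at 33254 ± 8830 CPM, and Mir191 at 13630 ± 34.4 CPM. Some of the highest means rested on unequal libraries. Mir126a (ENSMUSG00000065540.1), an endothelial microRNA in an exon of Egfl7 on chromosome 2 at 26591357 to 26591429, had 42849 counts in replicate 1 and 200301 in replicate 2. Mir99a had 108137 and 331489 counts, and Mirlet7d 181432 and 84309. In the exact binomial test of the 2 libraries, 19 of the 20 genes differed, 6 higher and 13 lower in replicate 2, and Mir191 did not (adjusted p = 0.199). With a minimum of 100 counts, which changes the scaling, 5 were higher and 15 lower.

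In summed CPM, over lists of unequal size, the neuronal list stood above each of the lists of other cell types and tissues in both libraries. By median log2(CPM + 1) the oligodendrocyte list (11.45) and the astrocyte list (9.63) stood above it (8.81). With either-strand counts the oligodendrocyte median was 0.22 against 8.50 for the neuronal list, and the oligodendrocyte sum 6263 CPM. Both Mir219a-2 and Mir338 overlap another microRNA gene, and that column sets their reads aside. The fall therefore does not bear on the level of the oligodendrocyte list. Mir127 alone gave 56482 of the 106756 CPM of the neuronal list. The neuronal list took 10.7% ± 0.753 of the counts (SD, n = 2) and had 17 of 20 members with 10 or more counts in both libraries. Its highest members were Mir127, Mir132 and Mir128-1, the last at 8694 ± 4603 CPM. The miR-9 and miR-181 families took 0.683% ± 0.0160, led by Mir181d, Mir181c and Mir181b-2. The oligodendrocyte list took 1.15% ± 0.128, with the widely expressed Mir23a at 5738 ± 1394 CPM, Mir219a-2 at 3511 ± 110 CPM and Mir338, in an intron of Aatk, at 2218 ± 224 CPM. The astrocyte and reactive glia list took 1.52% ± 0.261, led by Mir29a at 10528 ± 2605 CPM and Mir21a at 1920 ± 844 CPM. The neuronal sum was 9.60 times the oligodendrocyte sum in replicate 1 and 9.05 times in replicate 2, and it was 7.62 and 6.59 times the astrocyte sum. Mir127 and Mir134 belong to the neuronal list and to the Dlk1-Dio3 list, and Mir181a-1 to the miR-9 and miR-181 list and the astrocyte list. Mir128-1, Mir181b-2, Mir219a-2 and Mir23a each share 20 bases with another gene, so their counts are uncertain.

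The neural families miR-124 and miR-9 stood low in these counts. The 3 miR-124 genes had 12 counts together in replicate 1 and 9 in replicate 2, and the 3 miR-9 genes had 377 and 641. Each of these 6 genes shares a stretch of 22 bases with at least 2 other annotated microRNA genes, and reads that match several places are left out of the counts. The counts of these genes are therefore uncertain as levels. Detection also differed between genes with and without a near-identical copy elsewhere, over all symbols: 84 of 1087 genes that share 20 bases had 10 or more counts in both libraries (7.73%, 95% Wilson interval 6.28 to 9.47), against 327 of 1115 that share none (29.3%, 26.7 to 32.1). Among genes with a Mir symbol alone, a split chosen after seeing the data, the shares were 31.2% (25.8 to 37.0) and 35.0% (32.0 to 38.2), which overlap in their intervals.

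Among other cell types and tissues, the vessel wall list stood highest. It took 3.01% ± 1.95 of the counts, most of it from Mir126a, while Mir143, typical of smooth muscle, stood at 5984 ± 462 CPM. With either-strand counts, which set aside the reads of Mir126a, the vessel wall sum was 6809 CPM. The microglia and leukocyte list took 0.512% ± 0.149, led by Mir342 in an intron of Evl at 3413 ± 1281 CPM, and it shares Mir146 with the astrocyte list. The choroid plexus and ciliated epithelium list summed to 1594 ± 344 CPM, led by Mir204, in an intron of Trpm3, at 944 ± 370 CPM. The list of neighbouring brain and sensory regions took 0.342% ± 0.0641, of which Mir7b was the highest member at 2896 ± 713 CPM. The red blood cell list summed to 92.7 ± 35.0 CPM and the muscle list to 111 ± 4.92 CPM, of which Mir206 gave 103 ± 6.44 CPM. With either-strand counts, which set aside the reads of Mir451a and Mir486, the red blood cell sum was 25.7 CPM. The liver, pancreas and pluripotent cell list summed to 33.1 ± 0.433 CPM, of which the liver microRNA Mir122 gave 28.9 ± 1.80 CPM, and 7 of its 16 members had 0 counts in both libraries.

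**Figure D2:**
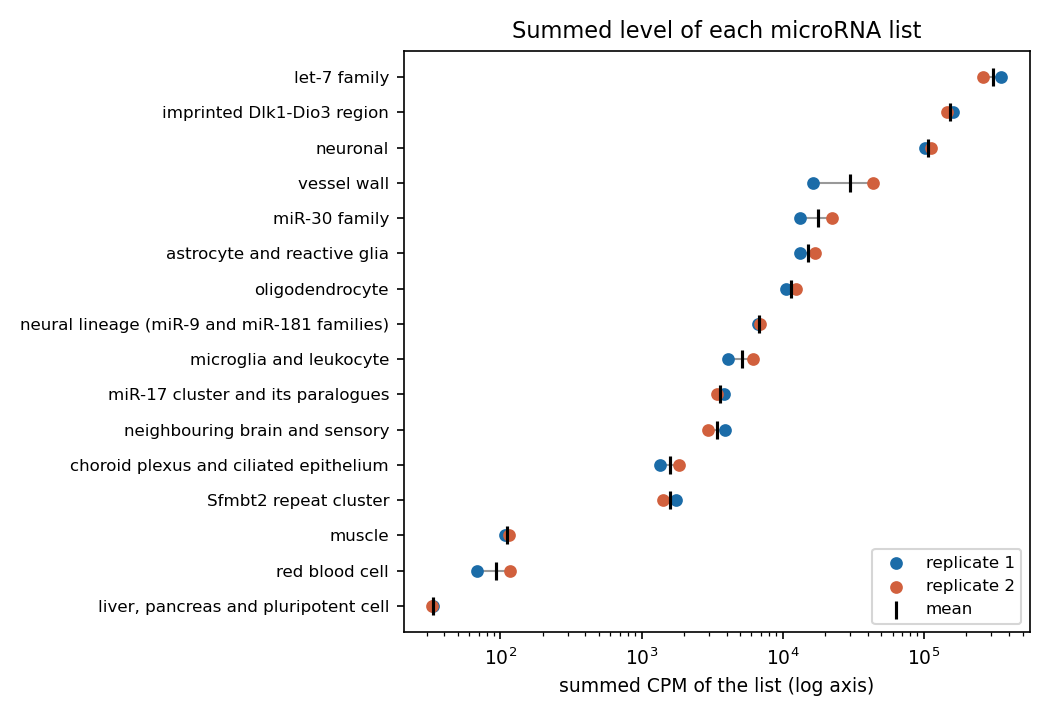
Summed CPM of each fixed list on a log axis, with 1 point per replicate and a bar at the mean of the 2. The let-7, Dlk1-Dio3 and neuronal lists lie above 100000 CPM in both libraries, and the muscle, red blood cell and liver lists lie between 32.8 and 117 CPM.

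Of the counts assigned to genes, the let-7 family took 30.9% ± 6.31, the miR-30 family 1.78% ± 0.636 and the miR-17 cluster with its paralogues 0.361% ± 0.0281. Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2, Mirlet7f-1 and Mirlet7f-2 share 20 bases with other genes, so their counts and the let-7 share are uncertain. In level, 13 of the 16 lists lay at or above the 95th percentile of 10000 random lists of the same size drawn from all genes in the files. Of these 2202 genes 1424 had 0 counts in both libraries, so the median of such a random list is mostly near 0 and is easily exceeded. The exceptions were the muscle list at percentile 90.0, the liver, pancreas and pluripotent cell list at 92.2 and the Sfmbt2 repeat cluster at 49.9. The muscle and liver lists lay at 44.2 and 45.6 without replicate 2 and at 41.7 and 42.4 with either-strand counts. With either-strand counts, which drop genes that overlap another, 11 lists reached the 95th percentile, as the oligodendrocyte list fell from 99.97 to 67.8 and the red blood cell list from 97.3 to 29.1. Against random lists of detected genes alone, 4 lists lay at or above the 95th percentile, namely the let-7 list at 100, Dlk1-Dio3 at 99.9, oligodendrocyte at 97.8 and neuronal at 96.1.

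The imprinted Dlk1-Dio3 region, whose microRNAs are transcribed from the maternal chromosome, was a main source of microRNA counts. Its 51 listed genes lie on the plus strand of chromosome 12 between 109563692 and 109747960 and took 15.4% ± 1.09 of the counts (SD, n = 2). Of these, 48 had 10 or more counts in both libraries, and 16 reached 1000 CPM in both. The 3 highest, Mir127, Mir487b (13968 ± 1882 CPM) and Mir433 (11365 ± 5243 CPM), held 53.1% of the region's mean CPM. Mir487b shares a 20-base stretch with another gene, so its count is uncertain. Mir770, in an exon of Meg3, stood at 10525 ± 7081 CPM, with 68403 counts in replicate 1 and 29133 in replicate 2. The list of the Sfmbt2 repeat cluster is named after another imprinted group of many similar hairpins. It was filled by symbol, wherever the gene lies, and summed to 1590 ± 232 CPM. Of its 81 genes, 67 had 0 counts in both libraries. Its highest member was Mir467d at 659 ± 30.6 CPM, and 14 other genes share a 20-base stretch with it, so its count is uncertain.

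**Figure D3:**
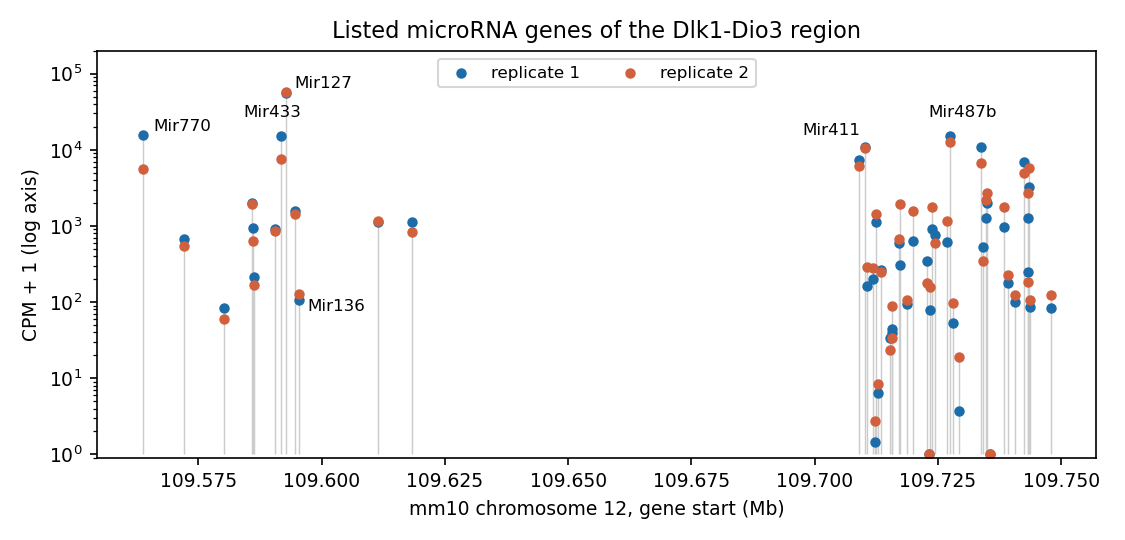
CPM + 1 on a log axis of the 51 listed microRNA genes of the Dlk1-Dio3 region against gene start on mm10 chromosome 12 in Mb, with 1 point per replicate. Mir127 stands highest at 56482 CPM on average, while Mir136, under 3 kb away, stands at 116 CPM.

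MicroRNAs of the same primary transcript differed strongly in their counts. How evenly different sequences were captured was not measured, so the ratios below are of counts and need not be ratios of level. In 13 of the 18 fixed sets, the highest gene exceeded the lowest by more than 10 times in both libraries. In 6 of the 13 the lowest gene shares 20 bases with another gene, so its count is uncertain, and in 1, that of Mir96, it lay at or under the counting floor, which leaves 6. Copies outside the annotated microRNA genes were not searched, so genes of these 6 sets may also have lost reads. Mir132 exceeded Mir212 by 53.6 times in replicate 1 (95% exact binomial interval 51.2 to 56.1) and by 36.1 times in replicate 2 (34.7 to 37.6). Mir127 exceeded Mir136 by 529 (483 to 581) and 454 (421 to 491) times. Mir23b exceeded Mir24-1 by 730 (587 to 920) and 506 (443 to 580) times, but Mir24-1 shares 20 bases with 2 other genes and its count is uncertain. Other sets were closer: Mir221 had 3.28 and 4.09 times the counts of Mir222, and Mir411 1.47 and 1.75 times those of Mir379. Mir23b and Mir411 each share 20 bases with another gene, so their counts are uncertain too. Mir181d had 1.53 times the counts of Mir181c in replicate 1 and 0.879 times in replicate 2. In the set of Mir183, Mir96 and Mir182, Mir96 had 1 count in replicate 1 and 0 in replicate 2, against 42 and 125 for Mir183.

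Replicate 2 differed from replicate 1 in many genes beyond counting error. Of 504 genes with 10 or more counts in total, 281 differed at an adjusted p below 0.05 in the exact conditional binomial test with Benjamini-Hochberg adjustment, 164 higher and 117 lower in replicate 2. Of the 313 tested genes with 100 or more counts, 147 were higher and 107 lower, and 122 and 130 when scaling and adjustment used those genes alone. Of the 281, 58 were higher and 26 lower by at least 2-fold, and 62.9% of the tested genes lay within 1.5-fold. Mir301 (ENSMUSG00000065589.1, in an intron of Ska2 on chromosome 11, 87113004 to 87113089) had 94 counts in replicate 1 and 4313 in replicate 2, a log2 ratio of 5.18. Mir1247, in an exon of Dio3os, had 43 and 1521 counts (log2 ratio 4.73), and Mir195a had 5739 and 77354 (3.47). Mir181a-2 had 68 and 1004 counts (3.52), and Mir200b 35 and 345 (2.87). In the other direction Mir26a-1, in an intron of Ctdspl on chromosome 9 at 119031796 to 119031885, had 932 counts in replicate 1 and 50 in replicate 2 (log2 ratio -4.36). Mir222 had a log2 ratio of -1.92, Mir669e -1.71, Mir221 -1.60 and Mir770 -1.51. Mir181a-2, Mir26a-1 and Mir669e each share 20 bases with another gene, so their counts are uncertain.

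The test counts reads and not animals: edgeR estimated a biological coefficient of variation of 0.425 between the libraries, and DESeq2 0.190 as its median gene-wise value and 0.442 as its fitted value. With a coefficient of variation of 0.1 built into the test 149 genes differed, and with 0.3, a value added after seeing the data, 14 did, 13 higher and 1 lower. Ranks agreed across genes, with Spearman's rho of 0.968 and Pearson's r of 0.976 over the 504 genes, which are not independent replicates.

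**Figure D4:**
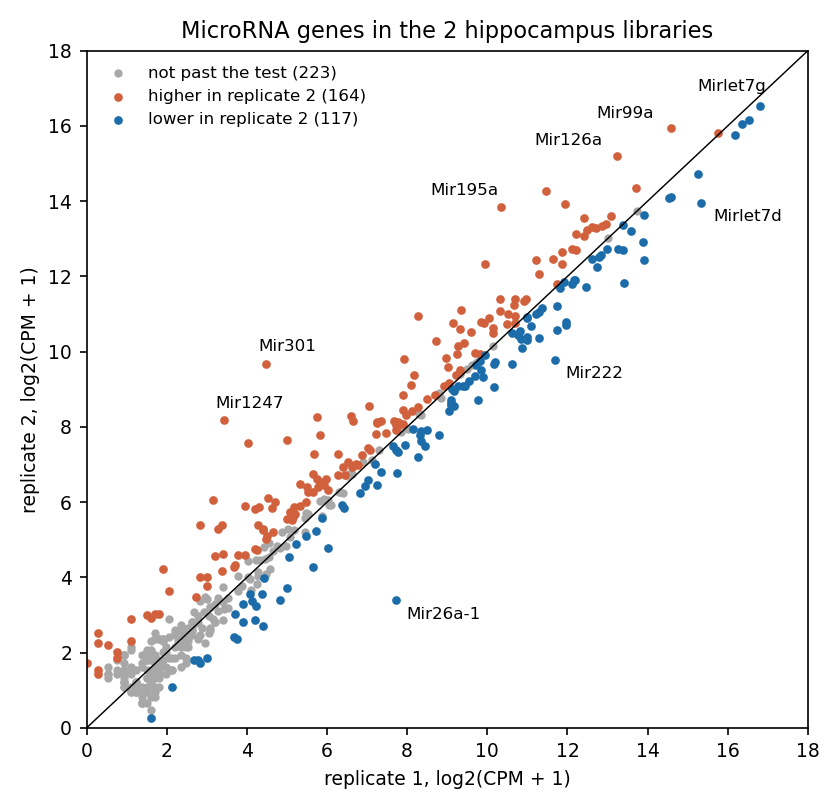
Log2(CPM + 1) of 504 microRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), coloured by the exact binomial test of the 2 libraries, with the diagonal of equal level. Orange points (164 genes) are higher and blue points (117 genes) lower in replicate 2, and among the labelled genes Mir301 lies farthest above the diagonal and Mir26a-1 farthest below it.

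The let-7 family was lower in replicate 2 as a group, and choroid plexus genes were higher. All 12 let-7 members were lower in replicate 2, in the total-count, DESeq2 and 100-count settings too, with a median log2 ratio of -0.42. That median lay at percentile 1.14 of 10000 random lists of the same size and expression. The percentile was 2.54 with a minimum of 100 counts and 4.8 with either-strand counts, both inside the 2.5 to 97.5 percentiles. Mirlet7d had the largest difference of the named members at -1.38. Of the 9 tested choroid plexus and ciliated epithelium genes, 7 were higher, 1 lower and 1 not past the test, with a median of 0.80 at percentile 99.0, and 5 were higher with DESeq2 size factors. These included Mir204 (0.80), Mir200b (2.87) and Mir34b (1.16), while Mir34c, in the same transcript as Mir34b, had -0.55. The Sfmbt2 repeat cluster had a median of -0.996 at a percentile of 0, with 5 of 9 tested genes lower, 1 higher and 3 not past the test, and Mir669c at -1.03. Mir669c shares 20 bases with 45 other genes, Mir467e with 16 and Mir467d with 14, so their counts and the ratio of this list are uncertain. The miR-17 cluster and its paralogues had a median of 0.60 at percentile 97.8, with 5 higher, 3 lower and 3 not past the test. Their summed CPM went the other way, from 3806 in replicate 1 to 3408 in replicate 2, because Mir93 (-0.61) and Mir17 (-0.35), the most abundant, were lower. These 4 lists lay outside the 2.5 to 97.5 percentiles, where 0.8 of 16 would lie by chance if members varied independently. Genes that share sequence had closer ratios than others here, and let-7, Sfmbt2 and miR-17 are sequence families. The choroid plexus list also holds related genes, such as Mir200b, which shares 12 bases with another member. More than 0.8 can therefore be expected. With a minimum of 100 counts 1 list lay outside those percentiles, the Sfmbt2 cluster.

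The other lists lay within those percentiles. In the neuronal list 12 genes were higher, 3 lower and 3 not past the test, with a median log2 ratio of 0.37 at percentile 90.2. Mir128-1, whose count is uncertain, stood at 1.12 and Mir132 at -0.48. The medians were 0.44 for the miR-9 and miR-181 families (5 higher, 3 lower), 0.18 for oligodendrocyte (2 higher, 1 lower) and 0.49 for astrocyte and reactive glia genes (5 higher, 1 lower). They were 0.43 for microglia and leukocyte genes (5 higher, 1 lower), 0.94 for red blood cell genes (3 higher, 0 lower, percentile 96.6), 0.18 for vessel wall genes (2 higher, 1 lower, though their sum rose from 16297 to 43888 CPM, most of it Mir126a) and 0.38 for the miR-30 family (4 higher, 2 lower). The Dlk1-Dio3 region had 23 genes higher and 21 lower with a median of 0.16, though its summed CPM was lower in replicate 2. With a minimum of 100 counts, which drops genes from the test and shifts log2 ratios by -0.13 through the scaling, these counts were 18 and 24 of 47 tested. In that setting 11 neuronal genes were higher and 5 lower, 1 oligodendrocyte gene higher and 2 lower, 4 astrocyte genes higher and 2 lower, 3 of 5 microglia and leukocyte genes higher and 1 lower (median 0.11, percentile 67.6), and 2 red blood cell genes higher and 1 lower (median 0.55, percentile 83.0). Median and sum also differed in sign for the neighbouring brain list (median 0.19, 4 higher, 1 lower), the muscle list (-0.41, none of 3 past the test) and the liver, pancreas and pluripotent cell list (0.19, none of 2 past the test). Adjusted over the list alone, 15 of the 18 tested neuronal genes, 8 of 9 choroid plexus genes, 12 of 12 let-7 genes and 44 of 49 Dlk1-Dio3 genes differed, the same counts as over all genes. For the miR-17 list 9 of 11 differed adjusted over the list alone against 8 over all genes, and for the Sfmbt2 cluster 7 of 9 against 6.

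Genes of the same transcript did not always move together between the libraries. In the transcript of Mir99b, Mirlet7e and Mir125a, in Spaca6 on chromosome 17 between 17830188 and 17830879, Mir99b had a log2 ratio of 2.77, Mir125a 0.43 and Mirlet7e -0.49. Mir99a stood at 1.34 and Mirlet7c-1, in the same intron of Mir99ahg, at -0.40. Mir221 and Mir222, 678 bp from end to end on chromosome X, were both lower in replicate 2, at -1.60 and -1.92.

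Counts on the strand opposite a gene were almost all those of an overlapping microRNA gene. Opposite-strand counts were 6.30% of the counts on both strands in replicate 1 (95% Wilson interval 6.28 to 6.32) and 8.69% in replicate 2 (8.67 to 8.72). The 64 genes that overlap a microRNA gene on the other strand held 99.95% and 99.97% of them, and in the other 2138 genes the opposite strand held 0.00365% and 0.00352% of the counts. In 29 genes with 10 or more opposite-strand counts the opposite strand exceeded the own strand in both libraries, and 27 of these have such a partner. Mir126b, chosen after its values were seen, had 0 own-strand counts and 42848 and 200298 opposite-strand counts, where Mir126a had 42849 and 200301 on its own strand.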

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

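Some reads fall outside the gene counts, and they stand far above the 3 counts that a count of 0 allows. Reads that matched several places numbered 5017585 in replicate 1 and 7087928 in replicate 2, and reads in no annotated microRNA gene 519412 and 792041. Opposite-strand counts, a further column of each file, numbered 295973 and 502699, and nearly all of them are reads that also count on the own strand of an overlapping gene. All tests in this part were chosen after the values were seen.

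The opposite-strand counts were set against the annotation. The lower of the 2 shares that lay in genes overlapping a microRNA gene on the other strand was 99.949%, and these are the reads of that overlapping gene. Loss of strand in the library is argued against by the genes without such a partner, where the upper 95% bound of the opposite-strand percentage was 0.00428. No biological explanation was tested, since the design gives 1 group.

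The reads that matched several places bear on the low counts of the miR-124 and miR-9 genes. Over the neuronal, miR-9 and miR-181 lists, 18 genes that share 22 bases with another gene had a lower median log2(CPM + 1) than 11 genes that share none (difference -3.39, one-sided permutation p = 0.0015). That difference rests on the miR-124 and miR-9 genes themselves: without them it was -0.64 for 12 genes against 11 (one-sided permutation p = 0.42). All 6 of those genes share 22 bases with other genes, so loss of their reads to the class that matches several places may account for the low counts, but it cannot be told apart from low abundance. What keeps it open is that the reads set aside, 1.14 and 1.34 times the gene counts, are not assigned to genes.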

How the results depend on the processing

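The number of detected genes (411), the 13 host transcript sets and the summed CPM of the 16 lists under TMM stayed within their limits in the alternatives run. The top 10 genes, picked anew in each setting, held 57.6% with either-strand counts, which drop genes that overlap another. They held 57.7% in replicate 1 alone and 51.8% in replicate 2 alone. The library difference was 149 genes with a coefficient of variation of 0.1 and 14 with 0.3 (added after seeing the data), both by construction stricter. The split was 164 higher and 117 lower, and 122 and 130 with a minimum of 100 counts, which left 313 genes and moved the scaling by -0.13 on the log2 scale. The spread as a coefficient of variation (square root of the dispersion) was 0.190 from DESeq2's median gene-wise value and 0.442 from its fitted value, and the cause was not tested. The Spearman correlation between the libraries was 0.912 with no minimum, where genes at or near 0 enter, and a pseudocount cannot move ranks. 4 lists were high against detected genes, by construction a stricter reference, and 1 list differed with 100 counts, which also changes the scaling and the random lists, and the cause was not tested; let-7 (-0.56), choroid plexus (0.67) and miR-17 (0.30) then lay inside the outer percentiles, as did let-7 with either-strand counts (-0.30). The gap in detection for genes with copies was -21.6 points, -36.3 with a minimum of 1 count, -12.6 with 100 and -3.86 among Mir symbols (added after seeing the data). 5 of the 20 highest genes and 8 list sums moved with either-strand counts; Mir126a, Mirlet7e and Mir191 fell to near 0 there. No paired analysis was possible because there is 1 group. The library difference cannot be rerun without a replicate.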

Other observations

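All tests in this part were chosen after the result was seen, except that of the Htr2c intron genes. The families and genes in this paragraph were also chosen after their values were seen. The 6 genes counted here as the miR-15, miR-16 and miR-195 group were all higher in replicate 2. Besides Mir195a, the log2 ratios were 1.54 for Mir15a, 1.89 for Mir16-1, 1.94 for Mir16-2, 0.84 for Mir497 and 0.35 for Mir15b. They lie as neighbours, Mir15a with Mir16-1, Mir15b with Mir16-2 and Mir195a with Mir497. Mir16-1 shares 20 bases with another gene, and Mir16-2 shares at least 12 bases with Mir16-1, so the counts of both are uncertain. The related Mir322, not counted in this group, was lower in replicate 2, at -0.36. The 3 genes of miR-99 and miR-100 were higher in replicate 2, at 1.34 for Mir99a, 2.77 for Mir99b and 0.65 for Mir100, while in the same host transcripts Mir125a stood at 0.43, Mir125b-1 at -0.03 and Mir125b-2 at -0.24. Both Mir125b-1 and Mir125b-2 share 20 bases with another gene, so their counts are uncertain. Of the 13 miR-344 genes on chromosome 7, 2 had 10 or more counts in both libraries, namely Mir344b with 97 and 361 counts and Mir344g with 27 and 12. Among 1028 genes without a Mir symbol 10 were detected, the highest being Gm23450 in an exon of Cacng8 at 729 ± 19.1 CPM. Snord43, annotated as a microRNA gene in an intron of Rpl3, had 136 and 1056 counts.

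Many microRNA genes differed between the 2 libraries. Activity of the host locus alone, as the whole cause, is argued against by 331 pairs of neighbours within 10 kb that share no stretch of 12 bases. These pairs, from 122 genes in 34 clusters, differed in log2 ratio by a median of 0.73 (95% bootstrap interval 0.51 to 0.88). That was no closer than reassigned ratios (0.75, percentile 40.32), where counting error gives 0.0524. Of these pairs 277 lie in the Dlk1-Dio3 region, and the other 54 had a median of 0.84 (0.63 to 1.13) at percentile 75.9, against 0.0603 from counting error. A part played by the host locus stays open, since neighbours need not share a transcript. Spread from library preparation, which would also part neighbours, was not measured. The rule for the host locus was revised with the values in view. Genes at separate loci that share 12 bases had closer ratios, a median difference of 0.49 over 112 pairs at percentile 0.11 of reassigned ratios, and percentile 1.77 without let-7 pairs. Capture that depends on the sequence may therefore contribute, but reads crossing between similar genes and regulation that follows the mature sequence would look alike, and a difference between the tissue samples stays open and untested, with 1 library each.

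Choroid plexus genes were higher in replicate 2 in 7 of 9 tested genes, with 1 lower and 1 not past the test. With DESeq2 size factors 5 of 9 were higher, and with a minimum of 100 counts 4 of 7, where their median lay at percentile 96.3. If that library held more choroid plexus tissue, microRNA genes in introns of Htr2c, a gene used strongly there, would be higher as well. Leaving out Mir1298 (log2 ratio 2.49), whose ratio had been seen, the other 4 tested had a median of 0.543 at percentile 90.8, with Mir448 at 0.81, Mir1264 at 0.84, Mir1912 at 0.28 and Mir764 at -0.10. Mir448 and Mir1264 were past the library test, while Mir1912 (4 and 7 counts) and Mir764 (32 and 36 counts) were not. The prediction asked for the 95th percentile or a median at or below 0, so more choroid plexus tissue cannot be told apart from no such difference with 4 genes.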
